A study of Mus musculus with 10 samples.

How the data were processed

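RNA was measured by sequencing in 10 mouse placentas of the C57BL/6 strain collected on gestation day 17.5. Per the labels' protocols, placentas were flash frozen, RNA was extracted with Trizol, and libraries were made with the Illumina TruSeq RNA kit. The authors deposited 1 table of whole-number read counts per gene symbol, with 44792 rows and a column for each of the 10 samples. Per the submitters' processing notes, reads were aligned with HISAT2 to the mouse genome build GRCm38. The HISAT2 version, the counting tool, the gene annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes can therefore not be told apart, and counts of near-identical paralogs and pseudogenes are uncertain, because it is not known how reads with several matches were counted.

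Samples were grouped by their titles into control (n = 2), LO-PE (n = 4) and EO-PE (n = 4). The series text speaks of 4 samples per group, and 2 control samples were analysed here. The labels do not say whether placentas of a group came from separate litters, so p-values measure the spread between these samples. Within groups, the 13 pairs of libraries differed by more than sampling noise: chi-square per degree of freedom lay between 7.62 and 49.6, and no library was counted as a repeat of another. The deposited counts held 27 rows whose names had turned into dates, with 0.23% of all counts. These rows stayed in the tests and are not named. The protein genes of the mitochondrial genome are not in the table, so 1 of the 38 gene lists was not tested.

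All tests were run in R 4.3.3. Genes with enough counts were kept with filterByExpr of edgeR 4.0.16 at its minimum count of 10 and minimum total of 15, which left 16973 genes. Library sizes were scaled with TMM factors, which lay between 0.907 and 1.11. Differences were tested with the quasi-likelihood F test of edgeR on the deposited counts of all 10 samples in 1 fit of group means, which gave the 3 contrasts. P-values were adjusted with the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05 and no fold threshold. Unless another tool is named, an adjusted p of a gene is from this test. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Levels are given as TMM-normalized counts scaled to a common library size (CPM) with the SD across libraries, and log2 CPM values carry a prior count of 2.

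Gene lists for placental and uterine cell types, for pathways and for RNA quality were fixed before the data were examined. The 37 lists with at least 4 tested members were compared with all other genes by camera of limma 3.58.1 on voom values, two-sided, with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were alternatives. Counts of members past the threshold are given over all tested genes and adjusted over the list alone.

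The genes named were set by a rule written before the data were examined. In each comparison the rule took the 8 largest rises and the 8 largest falls among genes past the threshold whose libraries did not overlap between groups and whose mean reached a CPM of 5 in the higher group, leaving out predicted genes without a proper symbol. It further took up to 4 members with the smallest p of each list that passed its test or had at least 3 members past the threshold. It always took 8 genes studied in preeclampsia: Flt1, Eng, Pgf, Vegfa, Hif1a, Nos3, Pappa2 and Htra1. Coordinates are 1-based on GRCm38 and come from the RefSeq annotation of that build, matched by symbol for 32097 row names and through 1 synonym for 1729. The genes printed from the lists are a subset of those the rule took, and this subset was chosen after their values were seen. Tests under other settings cover the genes of largest change, the 8 genes and that subset. Eomes, Il2rb and Itga1, and the genes of the tests in the closing part on a chromosome 12 cluster, were also named after their values were seen. The counts are per gene, so the span of the gene is given, and no exon or UTR is singled out.

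The edgeR script was tested on simulated counts of 16973 genes. Each fold was given to 50 genes in each comparison with control and to 100 in EO-PE against LO-PE. The changed genes were drawn from those with a mean CPM of at least 1, so recovery in genes of lower counts was not tested. For EO-PE against control it recovered 40% of 1.5-fold, 74% of 2-fold, 94% of 4-fold and 100% of 8-fold changes. For LO-PE against control it recovered 42%, 80%, 100% and 100%, and for EO-PE against LO-PE 69%, 85%, 100% and 100%. Unchanged genes made up 6.10%, 3.01% and 3.80% of the calls in the order given.

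The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals without TMM, no filter except a count above 0 (29837 genes), a stricter filter of a CPM of 1 in 4 samples (14601 genes), the 2 compared groups only, the replicate number as a block, and leaving out each library in turn. Where a control was left out, the lone control was assumed to vary like the other groups. Fits with a term for Y-linked reads, with the mean of the yolk sac list as a term, without the libraries concerned, and with correction for transcript length and GC content were added after the data had been seen. A library counted as holding Y-linked reads when Ddx3y, Eif2s3y, Kdm5d and Uty together had more than 100 counts. Transcript lengths and GC contents were medians over protein-coding transcripts of a reference annotation matched by symbol, used without coordinates.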

Results

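Placental messenger RNA was profiled on gestation day 17.5 in control mice and in mouse models that the labels call early-onset PE (EO-PE) and late-onset PE (LO-PE). PE is the usual abbreviation of preeclampsia, a hypertensive disorder of pregnancy. How the models were made is not given in the sources used here. The data comprised 2 control, 4 LO-PE and 4 EO-PE libraries. Total counts per library lay between 16930645 and 20205714, and between 21949 and 23745 genes had a count. The groups did not overlap in the number of genes with a count, which was 23313 to 23745 in EO-PE, 22608 to 22846 in control and 21949 to 22405 in LO-PE. The 10 most abundant genes took 14.1% to 14.9% of the counts in LO-PE, 10.1% to 12.9% in EO-PE and 10.8% to 11.8% in control.

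The libraries differed in the sex of the fetal tissue and in yolk sac transcripts. Transcripts of 4 Y-linked genes summed to between 1720 and 2471 counts in LO-PE 1, LO-PE 2, LO-PE 4 and EO-PE 2, and to between 0 and 4 counts in the other 6 libraries. Thus 0 of 2 control, 3 of 4 LO-PE and 1 of 4 EO-PE libraries held Y-linked reads. Xist, the RNA that silences an X chromosome in females, lay between 48.6 and 97.2 CPM in the libraries with Y-linked reads and between 488.1 and 1331 CPM in those without. The mean log2 CPM of the yolk sac list was 1.59 and 1.89 in the controls and 4.86, 5.37, 3.59 and 2.09 in LO-PE 1 to 4. In EO-PE 1 to 4 it was 1.37, 5.33, 4.11 and 2.08.

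**Figure D1:**
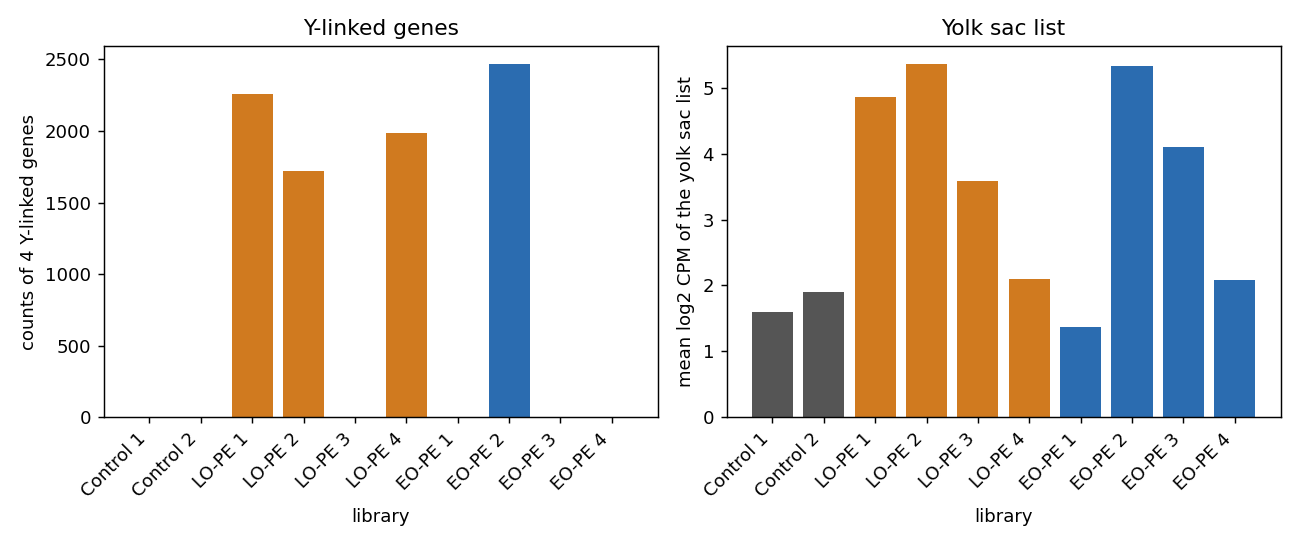
Counts of 4 Y-linked genes summed per library (left) and mean log2 CPM of the yolk sac gene list per library (right), with 1 bar for each of the 10 placenta libraries, grey for control, orange for LO-PE and blue for EO-PE. The 4 libraries with Y-linked reads stand between 1720 and 2471 counts, and both controls lie below 2 on the yolk sac axis.

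The comparison of EO-PE with control asked which placental transcripts differ in the early-onset model. Transcripts of the transferrin receptor Tfrc, which takes up iron, were 4.04-fold lower in EO-PE, at 348.8 ± 144 CPM (SD, n = 4) against 1408 ± 150 CPM (SD, n = 2) in control. The transcription factor Cebpb fell 3.91-fold, from 166.5 ± 44.0 to 42.6 ± 11.9 CPM. Granzyme and perforin genes, which encode the killing proteins of natural killer cells, fell together, among them Gzmf by 3.18-fold and Prf1 by 2.89-fold. Of 42 nuclear-coded subunits of the mitochondrial respiratory chain 9 fell, by smaller factors. In total 196 genes were higher and 523 lower in EO-PE among 16973 tested.

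Of the 10 tested members of the uterine natural killer list, 7 fell in EO-PE and 3 did not pass, and the count adjusted over the list alone was also 7. Gzmf (chromosome 14, 56205263 to 56211407) had a log2 fold change of -1.67 ± 0.27 (SE, edgeR adjusted p = 0.00732), with 23.5 ± 6.97 CPM in EO-PE and 74.9 ± 8.44 CPM in control. Gzmg and Gzmd had log2 fold changes of -1.59 ± 0.26 and -1.46 ± 0.25. The Gzm genes are close paralogs whose reads could have been split between them. Eomes, Il2rb and Itga1 did not pass, at log2 fold changes of -0.61 ± 0.46, 0.17 ± 0.13 and 0.22 ± 0.22. The list passed camera with an adjusted p of 0.000125, against an adjusted p = 0.757 with an estimated correlation. In the decidual stroma list 2 of 22 members fell, and 4 fell adjusted over the list alone. They were Cebpb (chromosome 2, 167688915 to 167690432), at -1.97 ± 0.23 (edgeR adjusted p = 0.00215), and the signalling protein gene Wnt4, at -0.53 ± 0.14 (edgeR adjusted p = 0.0469).

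Of the 42 nuclear-coded respiratory chain genes, 9 fell, none rose and 33 did not pass, while 18 fell and 1 rose adjusted over the list alone. The complex I subunits Ndufb5 and Ndufb9 fell 1.54-fold and 1.47-fold (edgeR adjusted p = 0.00512 and 0.0061). The list had a median log2 fold change of -0.29 and a camera adjusted p of 5.44e-07, against an adjusted p = 0.757 with an estimated correlation. Among antioxidant genes 4 of 31 fell, among them the glutathione peroxidase Gpx4 by 1.69-fold and the peroxiredoxin Prdx5 by 1.74-fold (edgeR adjusted p = 0.00442 for both). That list did not pass camera, with an adjusted p of 0.0825. Of 60 ribosomal protein genes 5 fell and 1 rose, and 9 fell and 1 rose adjusted over the list alone. Rps21 and Rps6 fell 1.71-fold and 1.60-fold, and such genes have many pseudogenes that can share their reads.

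In the labyrinth list, the zone of exchange between mother and fetus, 5 of 24 members fell and 6 fell adjusted over the list alone. These included Tfrc (chromosome 16, 32608896 to 32632794), at -2.01 ± 0.35 (edgeR adjusted p = 0.0117), and the cell fusion gene Synb, at 1.72 ± 0.75 CPM against 6.92 ± 0.13 CPM. Cebpa fell 1.94-fold and Tfeb 1.43-fold. Of 24 cholesterol genes 2 rose and 4 rose adjusted over the list alone. The LDL receptor Ldlr rose 1.47-fold and the sterol carrier Stard4 1.59-fold (edgeR adjusted p = 0.0297 and 0.0445). The labyrinth, decidual, ribosomal and cholesterol lists had camera adjusted p of 0.0088, 0.00826, 0.00826 and 0.0088. With an estimated correlation no list passed, and the 6 lists called had an adjusted p between 0.757 and 0.926.

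Several lists that did not pass camera held genes that changed. The antigen presentation genes B2m and H2-K1 fell 1.95-fold and 1.46-fold, and the apoptosis gene Bax and the stress gene Gadd45b fell 1.91-fold and 1.62-fold. Of the imprinted genes the growth restraint gene Cdkn1c fell 1.46-fold and Rtl1 rose 1.37-fold. The other genes with the largest rises were Edn2, an endothelin peptide, by 2.62-fold, Yod1 by 2.22-fold, Cyyr1 by 2.04-fold, Zfp329 by 2.01-fold, Gbp6 from 5.38 to 10.8 CPM, Rgs4 by 1.96-fold, Smim15 by 1.94-fold and Syt13 by 1.87-fold. Scand1 and Fmo2 completed the largest falls, at 3.10-fold and 2.96-fold. None of the 8 genes studied in preeclampsia passed. Flt1, the VEGF receptor whose soluble form is raised in the human disease, was at 1607 ± 438 CPM in EO-PE and 1396 ± 108 CPM in control (edgeR adjusted p = 0.631). Vegfa was at 188.7 ± 10.9 CPM and 229.2 ± 2.89 CPM (edgeR adjusted p = 0.0927). Eng, Pgf, Hif1a, Nos3, Pappa2 and Htra1 had log2 fold changes of 0.25 ± 0.20, -0.34 ± 0.21, 0.30 ± 0.11, 0.23 ± 0.21, 0.39 ± 0.27 and -0.22 ± 0.17.

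The calls of this comparison rested on the 2 control libraries and on the LO-PE libraries in the joint fit. With the compared groups only, 90 genes were called in place of 719, and 20 of the 34 named genes that passed lost their call. Without control 1 the count fell from 719 to 1 gene, and without control 2 it was 1795. Without EO-PE 3 it was 227, without EO-PE 4 346, without LO-PE 1 430 and without LO-PE 2 471. All 34 named genes that passed lost their call without control 1, with the same direction in each, while 30 kept it with a term for Y-linked reads and 22 with the yolk sac term. The 4 and 12 genes that lost it under these terms had median ratios of 1.00 and 0.947 to their log2 fold change without the term (lowest 0.905 and 0.767). Of the 10 fits without 1 library, Rtl1, Tfeb and Zfp329 kept their call in 2 and Cyyr1, Stard4 and Wnt4 in 3. The other named genes that passed kept it in 6 to 9. The list calls of the respiratory chain and ribosomal proteins ended without control 1 (camera adjusted p = 0.0547 and 0.42), those of decidua and cholesterol without control 2 (0.0852 and 0.234), and that of the labyrinth without control 2 or EO-PE 2 (0.0546 and 0.112). The labyrinth and cholesterol calls also ended with the yolk sac term (0.0652 and 0.0758), with which the endoplasmic reticulum stress list passed, downward (0.00195). The median log2 fold changes of the labyrinth and cholesterol lists were then -0.155 and 0.153, in place of -0.19 and 0.188. The calls fell to 248 with the yolk sac term and to 10 without the libraries that held Y-linked reads, where 3 EO-PE libraries were left. The share of higher genes among the calls was 27.3%, against 43.9% with DESeq2 and its own size factors, 11.1% with the compared groups only and 54.5% without control 2.

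**Figure D2:**
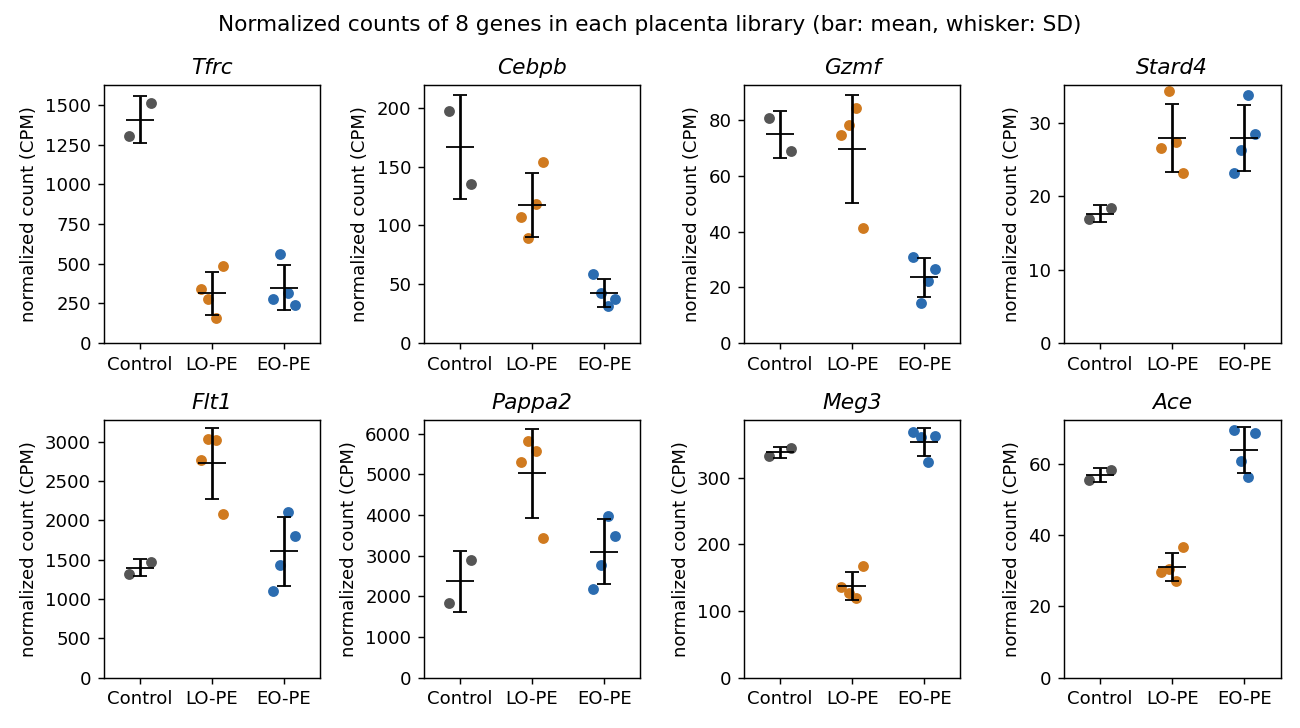
TMM-normalized counts scaled to a common library size (CPM) of 8 genes in each library, with 1 point per placenta, a bar at the group mean and a whisker of 1 SD for control (n = 2), LO-PE (n = 4) and EO-PE (n = 4). Tfrc is lower in both PE groups, at means of 314.2 and 348.8 CPM against 1408 CPM, while Meg3 is low in LO-PE alone among the 3 groups, at a mean of 137.5 CPM.

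The comparison of LO-PE with control asked the same of the late-onset model. Of 20 genes of the spongiotrophoblast, the hormone-secreting layer of the mouse placenta, 4 rose in LO-PE, while 5 of 20 endothelial and 3 of 14 smooth muscle genes fell. Flt1 rose 1.95-fold, from 1396 ± 108 (n = 2) to 2724 ± 450 CPM (SD, n = 4), and Pappa2, a protease that releases insulin-like growth factors, rose 2.12-fold, from 2368 ± 748 to 5030 ± 1090 CPM. The imprinted noncoding RNA Meg3 fell 2.46-fold, from 338.2 ± 8.34 to 137.5 ± 20.8 CPM. Tfrc fell 4.48-fold, to 314.2 ± 135 CPM. In total 332 genes were higher and 288 lower among 16973 tested.

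Of the 20 spongiotrophoblast genes 4 rose, 16 did not pass, and 11 rose adjusted over the list alone. The pregnancy-specific glycoproteins Psg23, Psg21 and Psg17 rose 1.66-fold, 1.68-fold and 1.88-fold (edgeR adjusted p = 0.0296, 0.0375 and 0.0441), and they are close paralogs. Of the 14 glycogen trophoblast genes 3 rose, and 7 rose and 1 fell adjusted over the list alone. The retinoic acid enzyme Aldh1a3 rose 3.48-fold, the prolactin relative Prl7c1 2.11-fold and the glycogen branching enzyme Gbe1 1.41-fold. No member of the giant cell list passed, and Hand1 was at 1.42-fold (edgeR adjusted p = 0.0685). The camera adjusted p of these lists were 2.06e-07, 0.000288 and 0.0335, against an adjusted p = 0.642, 0.642 and 0.906 with an estimated correlation.

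Of 20 endothelial genes 5 fell, and 14 fell and 1 rose adjusted over the list alone. Robo4, Tie1 and Icam2 fell 1.82-fold, 1.58-fold and 1.78-fold (edgeR adjusted p = 0.0208, 0.0249 and 0.0264). Of 14 smooth muscle genes 3 fell and 5 fell adjusted over the list alone. They were the actin Acta2, the kinase Mylk and the actin nucleator Lmod1, by 1.72-fold, 1.72-fold and 1.87-fold. Of 40 vasoactive and placental factors 4 rose and 2 fell, and 5 rose and 4 fell adjusted over the list alone. The angiotensin-converting enzyme Ace (chromosome 11, 105967948 to 105989964) fell 1.83-fold (edgeR adjusted p = 0.0108) and the angiotensin receptor Agtr1a 2.27-fold, while the plasminogen activator inhibitor Serpine1 rose 1.77-fold and the endothelin receptor Ednrb 1.36-fold. The endothelial and smooth muscle lists passed camera, with adjusted p of 7.38e-07 and 0.000245, against an adjusted p = 0.642 and 0.491 with an estimated correlation. The vasoactive list did not pass, with an adjusted p of 0.861 and a median and mean log2 fold change of opposite sign, -0.10 and 0.13.

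Among 36 imprinted genes 7 fell and none rose, and 9 fell and 3 rose adjusted over the list alone. Meg3 (chromosome 12, 109540996 to 109571729) had a log2 fold change of -1.30 ± 0.12 (edgeR adjusted p = 0.00126). Rtl1 (chromosome 12, 109564900 to 109604418) fell 1.75-fold, and its span overlaps that of Meg3, so their reads could have been mixed. Mest and Cd81 fell 1.66-fold and 1.35-fold. Dlk1, from the fibroblast list, fell 1.92-fold. Of 40 nutrient transporters 4 fell, and 12 fell and 1 rose adjusted over the list alone, among them the fatty acid carrier Cd36 by 1.72-fold and the vitamin carrier Slc5a6 by 1.49-fold. Of 24 labyrinth genes Tfrc and Cebpa fell, and 5 fell and 1 rose adjusted over the list alone. The camera adjusted p were 0.00153, 0.000363 and 0.00012, against an adjusted p = 0.642 for each with an estimated correlation.

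In the hypoxia and glycolysis list 3 of 35 members rose, and 5 rose adjusted over the list alone. P4ha1, a collagen hydroxylase, rose 1.73-fold, Ero1l 1.52-fold and Ak4 1.66-fold (edgeR adjusted p = 0.0108, 0.0151 and 0.0166). The median log2 fold change of that list was 0.13. With library totals in place of TMM it was -0.05, above the median of all genes, which that scaling moved to -0.18. Of 28 genes of endoplasmic reticulum stress the asparagine synthetase Asns rose 1.72-fold (edgeR adjusted p = 0.0208), and 8 rose and 1 fell adjusted over the list alone. Of 24 cholesterol genes Hsd17b7, Sqle and Stard4 rose and Ebp fell, while 9 rose and 2 fell adjusted over the list alone. Of 33 matrix genes the fibronectin gene Fn1 and the laminin gene Lamb1 rose 1.85-fold and 1.61-fold, and 9 rose and 2 fell adjusted over the list alone. Of 60 ribosomal protein genes Rps7 rose, and 0 did adjusted over the list alone. The camera adjusted p of these 5 lists were 0.0115, 0.000191, 0.00404, 0.000724 and 2.06e-07, against an adjusted p = 0.714, 0.642, 0.642, 0.642 and 0.694 with an estimated correlation. No member of the yolk sac list passed among 24, 12 rose adjusted over the list alone, and its camera adjusted p was 0.00208, against an adjusted p = 0.906 with an estimated correlation. With an estimated correlation no list passed, and the 14 lists called had an adjusted p between 0.491 and 0.906.

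The remaining largest rises were Dlg2 by 3.66-fold, the collagen gene Col15a1 by 3.41-fold, Gsg1l by 2.69-fold, Clec1b from 7.13 to 17.8 CPM, the pseudogene Atg4a-ps from 3.29 to 8.22 CPM, Enpp3 by 2.44-fold and Diras2 by 2.43-fold. The remaining largest falls were the long noncoding RNA Fendrr by 2.90-fold, the endothelial gene Ccm2l by 2.89-fold, Srcin1 by 2.63-fold, the muscle gene Ttn by 2.42-fold, Nova2 by 2.41-fold and Tmem44 by 2.39-fold. The steroid enzyme Hsd11b1 fell 1.49-fold and the estrogen sulfotransferase Sult1e1 rose 1.82-fold. Of the genes studied in preeclampsia, Flt1 (chromosome 5, 147561604 to 147726438) and Pappa2 (chromosome 1, 158711727 to 158960451) passed, with edgeR adjusted p of 0.0425 and 0.0488. Eng, Pgf, Vegfa, Hif1a, Nos3 and Htra1 did not, at log2 fold changes of -0.56 ± 0.20, 0.27 ± 0.22, 0.17 ± 0.09, 0.35 ± 0.11, -0.20 ± 0.21 and -0.29 ± 0.16.

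In place of 620 genes, 3 were called without control 1, of which 2 were among the 620, 153 without LO-PE 1, 30 without LO-PE 2 and 40 without LO-PE 3. With a term for Y-linked reads 11 genes were called, and with the yolk sac term 1. Of the 52 named genes that passed, Meg3, Tfrc and Ccm2l kept their call with the term for Y-linked reads, and Meg3 alone kept it with the yolk sac term (edgeR adjusted p = 0.0176). The 49 and 51 that lost it had median ratios of 0.987 and 0.86 to their log2 fold change without the term (lowest 0.587 and 0.602). Meg3 was the only one of them called without control 1. Flt1 and Pappa2 kept their call in 4 of the 10 fits without 1 library and lost it without control 1, control 2, LO-PE 1, LO-PE 2, LO-PE 3 or EO-PE 4 (highest edgeR adjusted p = 0.21 and 0.279). The list calls of giant cells, hypoxia, cholesterol, imprinted genes and ribosomal proteins ended without control 2 (camera adjusted p = 0.53, 0.327, 0.106, 0.148 and 0.327). That of giant cells also ended without LO-PE 1 or LO-PE 4 (0.0967 and 0.145) and that of hypoxia without LO-PE 3 (0.0677). The calls of giant cells, yolk sac and cholesterol ended with a term for Y-linked reads (camera adjusted p = 0.902, 0.687 and 0.0518). The yolk sac term ended those calls and that of endoplasmic reticulum stress (0.553, 0.866, 0.0718 and 0.057). With the term for Y-linked reads the median log2 fold changes of giant cells, yolk sac and cholesterol were 0.151, 1.41 and 0.299, in place of 0.379, 3.27 and 0.385. With the yolk sac term giant cells, cholesterol and endoplasmic reticulum stress were at 0.161, 0.202 and 0.137, the last in place of 0.263. The natural killer, erythroid and respiratory chain lists passed with the term for Y-linked reads, but not without a term or with the yolk sac term (camera adjusted p = 0.00985, 0.0307 and 0.0462), upward, upward and downward. Higher genes made up 53.5% of the calls, against 76.3% without control 2 and 10.9% with library totals in place of TMM, where the median log2 fold change of all genes was -0.18.

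**Figure D3:**
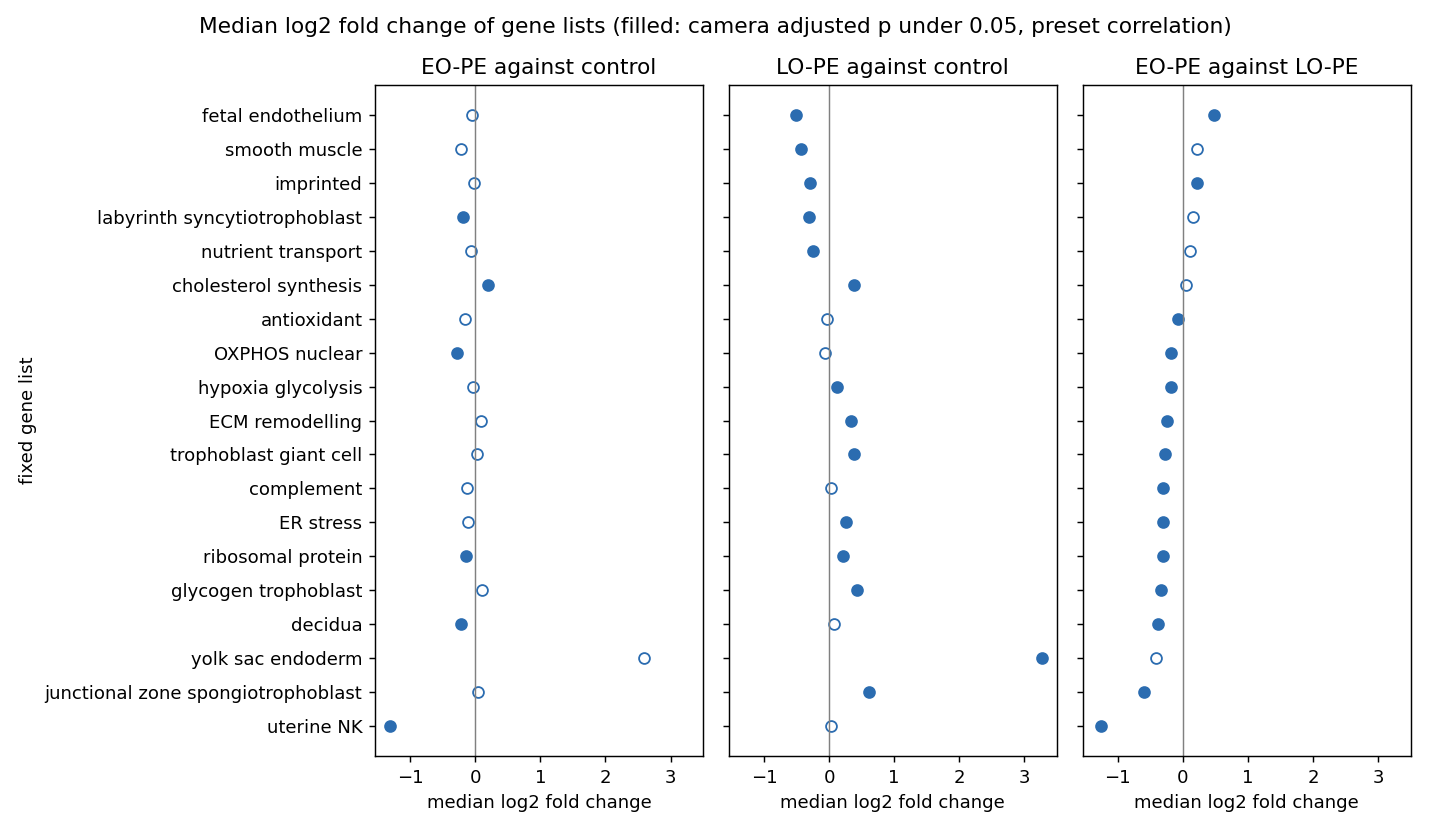
Median log2 fold change (horizontal axis) of the 19 gene lists that passed camera in some comparison (vertical axis), for EO-PE against control, LO-PE against control and EO-PE against LO-PE. Filled points have a camera adjusted p under 0.05 with the preset correlation and open points do not. The uterine natural killer list lies at -1.31 and -1.26 in the first and last panel and at 0.04 in the middle one.

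The comparison of EO-PE with LO-PE asked how the models differ from each other, with 4 libraries on each side. Of 36 imprinted genes 12 were higher in EO-PE, as were 6 of 20 endothelial genes, while 29 of 60 ribosomal protein genes, 11 of 28 stress genes of the endoplasmic reticulum, 8 of 20 spongiotrophoblast and 8 of 10 natural killer genes were lower. The EO-PE libraries also had more genes with a count than the LO-PE libraries, without overlap. Meg3 was 2.57-fold higher, at 353.7 ± 20.6 (n = 4) against 137.5 ± 20.8 CPM (SD, n = 4), and Ace was 2.06-fold higher, at 63.8 ± 6.42 against 31.0 ± 3.99 CPM. The stress transcription factor Atf4 was 1.86-fold lower, at 161.8 ± 15.4 against 301.5 ± 21.6 CPM. In total 1310 genes were higher and 1664 lower in EO-PE among 16973 tested.

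Of 60 ribosomal protein genes 29 were lower and none higher, and 38 were lower adjusted over the list alone. Rps25 was 1.76-fold lower and Rps6 1.94-fold lower (edgeR adjusted p = 0.000432 and 0.000618). Of 28 genes of endoplasmic reticulum stress 11 were lower and 13 adjusted over the list alone. Atf4 (chromosome 15, 80255184 to 80257545) had a log2 fold change of -0.90 ± 0.09 (edgeR adjusted p = 0.000196). Asns, the kinase relative Trib3 and the chaperone Dnajb9 were 2.22-fold, 2.32-fold and 1.55-fold lower. Of 42 respiratory chain genes 15 were lower and 1 higher, with the same numbers adjusted over the list alone, among them Ndufb9 by 1.41-fold and Uqcrq by 1.56-fold. Of 31 antioxidant genes 8 were lower in both counts, among them Gpx4 at 133.3 against 200.3 CPM and the heme oxygenase Hmox1, which was 1.44-fold lower. The median of the antioxidant list was -0.07. With library totals in place of TMM it was 0.09, below the median of all genes, which that scaling moved to 0.17. Of 35 hypoxia and glycolysis genes 11 were lower and 2 higher, and 14 were lower and 3 higher adjusted over the list alone. P4ha1 was 1.55-fold lower and the glycolytic enzyme Pgam1 1.54-fold higher. These 5 lists had camera adjusted p of 1.26e-13, 7.44e-06, 0.000142, 0.012 and 0.00165, against an adjusted p = 0.457, 0.457, 0.562, 0.457 and 0.457 with an estimated correlation.

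Of 10 natural killer genes 8 were lower in EO-PE in both counts, among them Gzmb by 3.47-fold, Gzmf by 2.95-fold, Gzmg by 2.71-fold and Prf1 by 2.94-fold. Of 22 decidual genes 5 were lower in both counts, with Cebpb 2.75-fold and the secreted protein gene Lgals3bp 1.51-fold lower. Of 20 spongiotrophoblast genes 8 were lower, and 14 were lower adjusted over the list alone, with Ceacam11 1.79-fold and Psg21 1.66-fold lower. Of 14 glycogen trophoblast genes 4 were lower and 1 higher, and 9 were lower and 1 higher adjusted over the list alone. Prl7b1 was 1.90-fold lower and the growth factor gene Igf2 1.60-fold higher. Of 18 giant cell genes 4 were lower and 1 higher in both counts, namely the prolactin relative Prl4a1 among the lower and the protease Ctsq as the higher one, at log2 fold changes of -0.92 ± 0.24 and 0.46 ± 0.12. Of 33 matrix genes 6 were lower and 9 adjusted over the list alone, with Fn1 1.51-fold lower. Of 21 complement genes 2 were lower and 1 adjusted over the list alone, with the inhibitor Serping1 1.77-fold lower. The camera adjusted p in this order were 6.87e-06, 0.000886, 5.19e-07, 0.0032, 0.0415, 0.00228 and 0.0415. With an estimated correlation they were an adjusted p = 0.457, 0.457, 0.457, 0.457, 0.613, 0.482 and 0.476.

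Of 36 imprinted genes 12 were higher and 1 lower, and 14 were higher and 1 lower adjusted over the list alone. Rtl1 was 2.40-fold higher, Zdbf2 2.39-fold and Kcnq1ot1 2.13-fold (edgeR adjusted p = 4.28e-05, 0.00153 and 0.00183), and Dlk1 was 1.85-fold higher. Of 20 endothelial genes 6 were higher, and 13 were higher adjusted over the list alone. The receptors Tek, Tie1 and Eng were 1.70-fold, 1.59-fold and 1.75-fold higher (edgeR adjusted p = 0.00227, 0.00234 and 0.00619). The camera adjusted p of these lists were 0.00165 and 0.000376, against an adjusted p = 0.457 for both with an estimated correlation. Of 40 vasoactive factors 4 were higher and 5 lower, and 5 were higher and 6 lower adjusted over the list alone, and the list did not pass camera at 0.509. Flt1, Vegfa, Pgf and Pappa2 were 1.69-fold, 1.37-fold, 1.52-fold and 1.62-fold lower in EO-PE (edgeR adjusted p = 0.0147, 0.00214, 0.0321 and 0.0411). Hif1a, Nos3 and Htra1 did not pass, at log2 fold changes of -0.05 ± 0.09, 0.44 ± 0.17 and 0.07 ± 0.14.

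The largest differences upward were Cyyr1 by 3.67-fold, Fendrr by 3.17-fold, Kctd12b by 3.16-fold, Tro by 2.74-fold, Gbp4 by 2.66-fold, Gbp9 by 2.62-fold, Tmem44 by 2.62-fold and Nova2 by 2.59-fold. Gbp4 and Gbp9 are interferon-induced paralogs, and Kctd12b and Tro lie on the X chromosome. Downward, next to Gzmb, Gzmf and Prf1, they were the transcription factor Pou3f1 by 3.03-fold, Scand1 by 2.97-fold, Dlg2 by 2.93-fold, the mitochondrial folate enzyme Mthfd2 by 2.93-fold and the pseudogene Rps15a-ps7 by 2.81-fold.

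With an estimated correlation no list passed, and the 14 lists called had an adjusted p between 0.457 and 0.613. Of the 35 splits of the 8 PE libraries into 4 and 4, 9 called at least as many lists, the real one included. The 2974 calls fell to 1766 without LO-PE 2, to 1935 without LO-PE 3 and to 1942 without EO-PE 4. They fell to 1578 with a term for Y-linked reads and to 33 without the libraries that held such reads, which left 1 LO-PE and 3 EO-PE libraries. Pappa2, Pgf and Serping1 each kept their call in 4 of the 10 fits without 1 library, Ctsq in 8 and Prl4a1 in 9, with highest adjusted p of 0.114, 0.0963, 0.1, 0.0728 and 0.0621. Pappa2 lost it without any of LO-PE 1, 2 and 3 and EO-PE 1, 2 and 4, and Pgf and Serping1 without any of LO-PE 1, 2 and 3 and EO-PE 2, 3 and 4. Pappa2 and Prl4a1 lost their call with a term for Y-linked reads (edgeR adjusted p = 0.0634 and 0.0653), at log2 fold changes of -0.80 and -0.94 in place of -0.70 and -0.92. With the yolk sac term Pappa2 lost it at -0.58 (edgeR adjusted p = 0.0834). The giant cell and complement lists kept their calls in 4 and 6 of those 10 fits, with highest adjusted p of 0.144 and 0.0976, and both ended with a term for Y-linked reads (0.382 and 0.0558) and with the yolk sac term (0.0803 and 0.0648). With these terms, in this order, the median log2 fold change of giant cells was -0.125 and -0.228, in place of -0.266. That of complement was -0.216 and -0.235, in place of -0.302. Higher genes made up 44.0% of the calls, against 82.3% with library totals in place of TMM, where the median log2 fold change of all genes was 0.17.

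Both contrasts with control share the 2 control libraries, so their fold changes are related even without any effect. Across genes, which are not independent replicates, the log2 fold changes of EO-PE and LO-PE against control had a Pearson r of 0.59. In 20 simulations of unchanged groups with the same design the mean r was 0.68. The covariance was 0.165, against a simulated mean of 0.0725 and a highest simulated value of 0.0796, a difference of 0.0925. Both controls lacked Y-linked reads and had low yolk sac transcripts, which the simulations did not copy. The excess can therefore not be read as an effect shared by the models alone. Of all genes 66.7% had the same sign, against 73.1% in the simulations. Among the calls, 31 genes were higher in both and 41 lower in both, including Tfrc and Cebpa, against 3.83 and 8.87 for independent lists. Calls against the same controls are not independent, and the 2 controls are too few to be split, so the part of this overlap that comes from them was not measured.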

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

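The tests for fetal sex in the group comparisons, for yolk sac tissue, for control 1 and for decidua were chosen only after the results were seen. The 2974 genes whose change against control differed between EO-PE and LO-PE are those called in EO-PE against LO-PE above. Of these 1310 were higher and 1664 lower in EO-PE, and control levels cancel out of the difference. Among 324 groups of 4 libraries (125 genes and 37 lists in both PE groups), 19 held a library far from the other libraries of its group, where chance gives about 1 in 20.

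In LO-PE 4, Prf1 was at 6.39 CPM against 11.9 to 12.8 CPM in the other LO-PE libraries, and Gzmb at 2.82 against 5.74 to 6.21 CPM. In the same library Ldlr was at 59.5 CPM, Fn1 at 11800 CPM, and the complement list mean at 3.3 log2 CPM. LO-PE 2 stood apart in Mylk, at 31.6 CPM, and in Plat, at 57.4 CPM. LO-PE 3 stood apart in Sult1e1, at 68.8 CPM, and in the sex-linked list mean, at -0.489 against 4.75 to 5.07 in the LO-PE libraries with Y-linked reads. EO-PE 2, the EO-PE library with such reads, had a sex-linked mean of 5.21 and Slc40a1 at 320 CPM. EO-PE 1 stood apart in Serping1, at 181 against 80.2 to 94.6 CPM, and in Plat, at 108 CPM. In that library Rtl1 was at 94.6, Syt13 at 11.1 and Nova2 at 8.31 CPM, and the giant cell list mean was 8.47 log2 CPM. Nos3 was at 3.88 CPM in EO-PE 3 and Pou3f1 at 2.49 CPM in EO-PE 4.

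EO-PE and LO-PE differed in 2974 genes. Of the 35 splits of the 8 libraries into 4 and 4, only the real one, 1 split, called as many, and the highest other called 21. Chance is thus unlikely for the gene count but not excluded, since 1 of 35 is the smallest share these splits can give. The splits also treat the libraries as independent, and their litters are not known. For the gene lists chance stays open, since 9 of the 35 splits, the real one included, called at least its 14 lists, and the highest other called 19. With a term for Y-linked reads the called genes kept a median ratio of 0.959 of their log2 fold change (quartiles 0.872 and 1.05). With length and GC trends removed it was 0.91 (0.785 and 1.02, with a length for 81.8% of the genes). The genes were chosen by the main fit, so both ratios were partly fixed in advance. Over all tested genes 1578 were still called with the term for Y-linked reads, so fetal sex may not be the whole source. With length and GC trends removed, 2486 of the 13752 genes with a length were called, so these trends may not be the whole source either. Differences in litter, handling or library complexity (23313 to 23745 genes with a count in EO-PE against 21949 to 22405 in LO-PE) and the models themselves stay open.

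LO-PE differed from control in 620 genes. With a term for Y-linked reads these genes kept a median ratio of 0.986 of their log2 fold change (quartiles 0.881 and 1.08), with the yolk sac term 0.868 (0.791 and 0.945), and without control 1 0.954 (0.846 and 1.09). The direction was the same in 620 of 620 genes each time. The 620 genes were chosen by the main fit on the same libraries, which favours small spread within groups. Kept folds were thus partly fixed in advance and cannot exclude fetal sex, yolk sac tissue or control 1 as a source. Of these genes 11, 1 and 2 were still called, with a median SE of 0.161, 0.147 and 0.163 in place of 0.133 and a median size of 0.619, 0.548 and 0.612 in place of 0.648, and how much of the loss comes from either was not tested. A part played by fetal sex, yolk sac tissue or control 1, and the models themselves, stay open. The spongiotrophoblast list was higher in LO-PE than in control (median log2 fold change 0.615). The labyrinth, endothelial and smooth muscle lists were lower (-0.304, -0.501 and -0.434). The share of each tissue zone in the samples was not measured, so it was not told apart from RNA level per cell. Both controls lacked Y-linked reads and had low yolk sac transcripts.

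Granzyme and perforin genes were lower in EO-PE than in LO-PE and control. With a term for Y-linked reads the 8 natural killer genes called lower in EO-PE than in LO-PE had a median ratio of 1.25 of their log2 fold change (quartiles 1.20 and 1.30), and 8 of 8 were called. These 8 were chosen by their call without the term, so this was partly fixed in advance. The median log2 fold change of all 10 tested members against LO-PE went from -1.26 to -1.67 with the term, which argues against fetal sex. Between EO-PE and LO-PE the mean of all 10 tested natural killer genes differed by -1.10 log2 units and that of the decidual stroma list by -0.386, and the difference of -0.717 had an exact two-sided permutation p of 0.0286, the smallest that 70 assignments can give. The 3 members other than granzymes and perforin were lower in EO-PE too, with a difference of -0.322 (exact two-sided permutation p = 0.0286). Their difference from the stroma list was 0.0641 (exact permutation p = 0.886), so a smaller share of decidua in EO-PE stays open. The placenta may also make some stromal transcripts, and a loss would then show less in that list. Less granzyme RNA per cell and a different number or kind of natural killer cells in EO-PE stay open too.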

How the results depend on the processing

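The fits with terms for Y-linked reads and yolk sac transcripts, those without the libraries concerned, and the correction for length and GC content were chosen after the data had been seen. The genes called in EO-PE against control (719), LO-PE against control (620) and EO-PE against LO-PE (2974) numbered 1436, 1539 and 3453 with DESeq2, 1349, 1445 and 3284 without a filter, 533, 1729 and 4045 with library totals, and 90, 1003 and 3322 with the compared groups only. With the replicate number as a block they were 79 (3.8% higher), 210 and 1902. Libraries of LO-PE and EO-PE with the same number had residual correlations of mixed sign (-0.139, 0.195, -0.0658 and 0.0629), too few to settle pairing. With a term for Y-linked reads they were 688, 11 and 1578, with the yolk sac term 248, 1 and 2304, without libraries with Y-linked reads 10, 1 and 33, and with the libraries of a yolk sac list mean of 3 or less 1, 6 and 7. The last 2 settings use fewer samples, and the cause of the other changes was not tested. Leaving out 1 library gave 1 to 1795, 3 to 929 and 1766 to 3324 genes. Without control 1 the first 2 counts were 1 and 3, and without control 2 the first was 1795. RLE factors, limma-voom and the stricter filter gave counts within 1.5 times of the main ones.

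The 6, 14 and 14 gene lists called by camera were 0, 0 and 0 with an estimated correlation (0, 2 and 1 at an unadjusted p under 0.05) and 0, 1 and 11 with fry (8, 9 and 20). Leaving out 1 library gave 4 to 9, 10 to 15 and 12 to 18. The lists, among them those of the short ribosomal protein genes, were not tested with the correction for length and GC content. The correlation of fold changes, EO-PE against control with LO-PE against control (0.594), was 0.672 with DESeq2, 0.494 with the term for Y-linked reads, and 0.464 (without EO-PE replicate 2) to 0.743 (without Control replicate 2) with 1 library left out. Of the named genes, 4 that were not called reversed. Vegfa in LO-PE against control went from 0.17 to -0.0055 and Hif1a in EO-PE against LO-PE from -0.05 to 0.11 with library totals, which shift the median of all genes by -0.177 and 0.171. Nos3 in LO-PE against control went from -0.20 to 0.047 without control 2 (-0.425 to 0.047 over the left-out libraries), and Htra1 in EO-PE against LO-PE from 0.07 to -0.039 without LO-PE 1 (-0.039 to 0.18). The cause was not tested.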

Other observations

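The cluster test below was chosen only after the result was seen, and its form was revised after a first version had been seen that also counted 5 genes lying within longer ones.

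Several gene groups not described above held genes that differed between EO-PE and LO-PE while their lists did not pass camera. Of 17 macrophage genes 4 were lower and 1 higher in EO-PE, the lysosomal protein Cd68 by 1.61-fold lower and the hyaluronan receptor Lyve1 by 1.65-fold higher (edgeR adjusted p = 0.00197 and 0.00654), and the list had a camera adjusted p of 0.122, against 0.0316 with the term for Y-linked reads. Of 23 immediate early genes 3 were higher and 5 lower, with Junb 1.66-fold lower and the nuclear receptor Nr4a1 1.70-fold higher, and of 28 apoptosis genes 2 were higher and 4 lower, with Bax 1.68-fold and Bcl2l1 1.45-fold lower (camera adjusted p = 0.222 and 0.539). Of 33 interferon genes 2 were higher and 4 lower, with Gbp7 1.72-fold higher and B2m 1.75-fold lower (camera adjusted p = 0.784). The protease inhibitor A2m of the coagulation list was 2.30-fold lower, and the cholesterol enzyme Fdft1 1.61-fold lower.

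Of 40 nutrient transporters 6 were higher and none lower, with Cd36 1.80-fold higher (edgeR adjusted p = 0.00326), and the labyrinth iron exporter Slc40a1 was 1.45-fold higher. Of 14 smooth muscle genes 3 were higher, with Acta2 1.62-fold and Mylk 1.64-fold higher. Neither list passed camera (adjusted p = 0.0859 and 0.0678). Plat was 1.48-fold higher and lost its call with the term for Y-linked reads (edgeR adjusted p = 0.15) and with the yolk sac term (0.0903), at log2 fold changes of 0.50 and 0.47 in place of 0.56, and without LO-PE 1, LO-PE 3 or LO-PE 4 (highest 0.0944). Over the comparisons 18 of the 37 lists passed camera in none. Among these, the largest adjusted p in EO-PE against LO-PE included heat shock genes at 0.924 and erythroid genes at 0.937.

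A hypothesis is that LO-PE placentas had lower expression along the imprinted Dlk1 to Meg3 cluster of chromosome 12. Among 3 other tested genes in a fixed window around the cluster that lie outside longer genes, 2 were called higher in EO-PE than in LO-PE, Rian at 0.83 ± 0.10 and Mirg at 0.72 ± 0.20 log2 units, and Gm6988 was not (-0.74 ± 0.48). Against control, Rian was lower in LO-PE (-0.65, edgeR adjusted p = 0.0208), and Mirg and Gm6988 did not pass (-0.69 and -0.09, edgeR adjusted p = 0.111 and 0.947). For EO-PE against LO-PE a two-sided Fisher exact test against the other tested genes gave p = 0.0169 (odds ratio 23.9). A change along the cluster may thus extend past the named genes, but some of the genes may share 1 primary transcript, so they are not independent. The span of Rian (109603945 to 109661716) overlaps the end of that of Rtl1, 1 of the genes that raised the hypothesis. The strand setting is not given in the sources used here, so reads of neighbouring genes could be mixed.

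A further hypothesis is that ATF4 target genes were lower as a set in EO-PE than in LO-PE. It arose from Atf4, Asns and Trib3, which were lower in the same EO-PE libraries. A list of 38 known targets was fixed before its values were read, of which 36 were in no other list and tested. Their mean differed by -0.36 log2 units, with an exact two-sided permutation p of 0.0286, the smallest that 70 assignments can give. This test did not compare the targets with other genes, and the decidual stroma list reached the same p. Of the targets 18 were called lower, 0 higher and 18 did not pass, against 1664 lower and 1310 higher among all 16973 tested genes. Lower ATF4 activity in EO-PE, or higher activity in LO-PE, is a candidate explanation. The set was not tested against control, so neither was told from the other.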
